A study of Mus musculus with 6 samples.

How the data were processed

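Naive CD4 T cells from mouse spleen were cultured under Th17 conditions with 10 nM pemafibrate or vehicle until day 2 and for 2 days more in IMDM with 10% serum, per the labels' protocols. Libraries were made from 1.0 µg of total RNA with a stranded mRNA kit, per the labels' protocols. The treatment label of each sample gave its group, with 3 samples in each.

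Per the submitters' processing notes, the tools were bcl2fastq, Trimmomatic 0.35, HISAT2 2.1.0, featureCounts 1.4.6 and edgeR, and the builds were GRCm38 and mm10. The gene annotation and the strand setting of the counting were not given in the sources used here, so reads of overlapping genes, antisense genes and near-identical copies, ribosomal protein pseudogenes among them, cannot be told apart. The authors deposited one table of RPKM, reads scaled to gene length and library size, for 24421 genes in the 6 samples. The same table holds the authors' own log2 fold change, p-value and adjusted p-value between the groups, per the file headers; the sign of that log2 fold change is pemafibrate over vehicle, judged from the RPKM columns. The authors' deposited rank by p-value is an other kind of column and was not used.

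The deposited unit is RPKM, so the planned count models were not run, and voom on the reads recovered from the RPKM values took their place. The RPKM steps of each gene were whole multiples of one value per sample, and for all 16822 genes above 0 the ratios between samples gave whole reads (100% of nonzero values within a relative tolerance of 1e-06). For a gene with few reads these are the smallest whole numbers with the observed ratios. The other 7599 genes were at 0 in all samples. The implied library sizes were 14935351 to 18322467 reads, so that 1 read in a gene of 2000 bases was worth at most 0.0335 RPKM. The precision of read numbers covers counting error only.

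Genes with a mean of at least 0.5 RPKM over the 6 samples, 11360 in all, were tested on log2(RPKM + 0.5) with limma 3.58.1 in R 4.3.3 (trend in the prior variance, no further scaling), comparing pemafibrate with vehicle, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 differences are on that scale, which understates the change of low genes. Before the data were examined 39 gene lists were fixed, and 33 with at least 5 tested members were compared with other genes by camera (preset inter-gene correlation of 0.01), with an estimated correlation and with fry (which does not compare a list with other genes). Named genes follow a rule set in advance: the 10 highest and 10 lowest log2 differences among called genes whose groups do not overlap, leaving out predicted genes, pseudogenes and receptor segments (1 lower gene was skipped); a preset panel of T cell, PPAR and metabolic genes; and up to 4 members per list with the smallest p. Some genes that the rule takes are not reported here. Other called genes and members are named where a count or a marker level needs them, and were chosen after their values were seen. Gene positions come from RefSeq for the same build, GRCm38, which matched 24313 symbols (99.6%).

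The alternatives were pseudocounts of 0.1 and 1, no filter and a filter at 2 RPKM, median ratio scaling, quantile normalization, array weights, robust variance moderation, the title number as a block, other thresholds, and leaving out each sample. After the data were seen, voom on the recovered reads (genes with a mean of at least 10 reads), a filter at 10 recovered reads and removal of a per-library trend with gene length were added. The procedure was tested on simulated data for this comparison with 50 genes changed at each fold among 11375 tested: it recovered 56% at 1.25-fold, 86% at 1.5-fold, 98% at 2-fold and 100% at 3-fold, and 6 of 182 called genes were unchanged ones. The simulation drew genes independently, with the same dispersion (0.0012) for every gene and no structure shared within libraries. These rates hold for that setting only and may be better than those in the real data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.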

Results

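Messenger RNA was measured in mouse CD4 T cells that had been isolated from spleen as naive cells and driven towards the Th17 state, the helper T cell type that makes interleukin 17. The cultures received pemafibrate, a selective modulator of the nuclear receptor PPARalpha, at 10 nM or vehicle up to day 2, followed by 2 days in medium with 10% serum. There were 3 vehicle samples, which carry the numbers 3, 4 and 7 in their titles, and 3 pemafibrate samples, numbered 3, 7 and 8. The labels do not say whether the samples came from separate animals or cultures, so the p-values measure only the spread between these samples, which may be technical. The deposited RPKM values imply libraries of 18102216, 17093142 and 17297576 reads for vehicle 3, 4 and 7, and of 18322467, 14935351 and 17661872 reads for pemafibrate 3, 7 and 8.

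The vehicle and pemafibrate samples lay on opposite sides of the first principal component of log2 expression, which held 26.4% of the variance. Vehicle samples had scores from -11.8 to -7.05 and pemafibrate samples from 6.77 to 11.3. The second component, with 24.9%, did not follow treatment: vehicle 7 (-12.1) and pemafibrate 3 (-10.6) lay at one end, and vehicle 4 (9.37) and pemafibrate 8 (10.4) at the other. Pearson correlations across the 11360 tested genes, which are not independent replicates, ran from 0.992 to 0.993 within groups and from 0.990 to 0.992 between them. Every pair within a group differed by more than sampling noise, with a chi-square per degree of freedom between 2.78 and 8.27.

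The main comparison asked which genes differ after pemafibrate under Th17 conditions. Pemafibrate-treated cells had more RNA for the cytokine genes Il9 and Il22 and the chemokine receptor genes Ccr4, Ccr6 and Ccr8. They had less RNA for the cytokine gene Il21, for the interleukin 23 receptor gene Il23r, for the transcription factor genes Maf and Id2, and for the chemokine receptor gene Cxcr4. Most differences were modest: among called genes with a mean of at least 10 reads, the highest fitted fold was 2.39, for Nupr1. With limma and Benjamini-Hochberg adjustment, 40 of 11360 genes passed an adjusted p of 0.05, 15 higher and 25 lower in pemafibrate, and 11 of them reached 1.5-fold. In each of the 40 the 3 pemafibrate samples lay wholly above or wholly below the 3 vehicle samples. Of all tested genes, 1701 (14.97%) showed such separation, against 10% by chance for 3 against 3, and 1098 had an unadjusted p under 0.05, against 568 expected. Splits of the 6 samples that do not follow treatment gave 214 to 1368 genes at that threshold. An excess over 568 is therefore not particular to pemafibrate.

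Among genes called by limma with a mean of at least 10 reads, the one rising most was Nupr1, a small stress-induced nuclear protein (chromosome 7, 126623246 to 126625470, GRCm38). Nupr1 went from 1.24 ± 0.376 to 3.62 ± 0.552 RPKM (mean ± SD, n = 3 per group), with a log2 difference of 1.26 ± 0.18 (SE) and a limma adjusted p of 0.0409. Il9 (chromosome 13, 56479277 to 56482257) rose from 42.2 ± 6.74 to 76.4 ± 2.41 RPKM, a log2 difference of 0.86 ± 0.10 (limma adjusted p = 0.0314). Akr1c18, which encodes a hydroxysteroid dehydrogenase that inactivates progesterone, rose from 23.7 ± 3.16 to 43.2 ± 1.93 RPKM (log2 difference 0.86 ± 0.09). Sh2d1a, the gene for the signalling adaptor SAP, rose by a log2 difference of 0.62 ± 0.09, from 33.6 to 52.0 RPKM. Ccr8 (0.55 ± 0.06), Ccr6 (0.53 ± 0.05), Ms4a4b (0.51 ± 0.05), Sytl1 (0.47 ± 0.07) and Il22 (0.42 ± 0.06) rose less. B4galnt4 (-0.70 ± 0.08), Lgr4, a receptor for R-spondins (-0.65 ± 0.09), Kctd12 (-0.63 ± 0.09) and Zak, a MAP kinase kinase kinase (-0.57 ± 0.08), fell. Cd24a, a surface glycoprotein gene (chromosome 10, 43579169 to 43584265), had the smallest p and fell from 43.9 ± 1.495 to 28.7 ± 0.551 RPKM (log2 difference -0.60 ± 0.04, limma adjusted p = 0.00592). Cxcr4, the receptor for CXCL12, fell from 59.7 ± 2.47 to 41.1 ± 1.18 RPKM (log2 difference -0.53 ± 0.04).

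**Figure D1:**
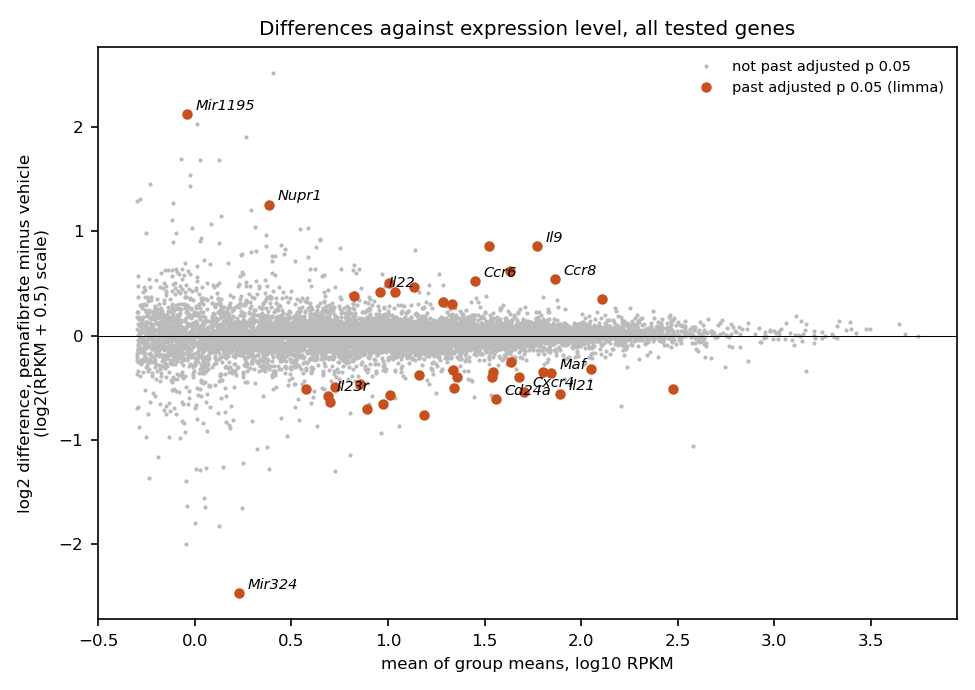
Log2 difference between pemafibrate and vehicle (vertical axis, on the log2(RPKM + 0.5) scale) against the mean of the group means in log10 RPKM (horizontal axis) for the 11360 tested genes, with the 40 genes past an adjusted p of 0.05 as large points. The microRNA genes Mir324 and Mir1195, at the vertical extremes of the large points, rest on few reads.

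The microRNA genes Mir324 and Mir1195 also passed, but on very few reads. The smallest whole read numbers that give the deposited ratios were 7, 4 and 4 in vehicle 3, 4 and 7 against 1, 0 and 0 in pemafibrate 3, 7 and 8 for Mir324, and 0, 0 and 0 against 1, 2 and 1 for Mir1195, so no fold is given. An adjusted p under 0.05 was held by 291 genes in the authors' deposited table, 117 higher and 174 lower. Of these, 279 were tested here, and limma called 38 of them. All 279 had the same sign, which is no independent support, since both sets of values come from the same 6 libraries. The authors' deposited table shares 38 of the 40 genes, all but Mir324 and Mir1195. The count of 40 rested on every library: limma called 2 genes without vehicle 3, 8 without vehicle 4, 18 without vehicle 7, 25 without pemafibrate 3, 15 without pemafibrate 8 and 0 without pemafibrate 7, where 771 had an unadjusted p under 0.05. With voom on the recovered reads the count was 148, with array weights 140, and with no expression filter 7.

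Th17 genes as a group were lower after pemafibrate, though single members went both ways. Of 22 members of the Th17 core list, all measured, limma called 6 over all genes, 4 lower and 2 higher, and voom on the recovered reads called 10, 9 lower and 1 higher. Il21, a cytokine that promotes Th17 differentiation, fell from 93.0 ± 1.96 to 63.1 ± 3.85 RPKM (log2 difference -0.56 ± 0.05, limma adjusted p = 0.0104). Il23r fell from 5.94 ± 0.422 to 3.83 ± 0.141 RPKM, Maf from 78.7 ± 2.20 to 61.3 ± 3.96 RPKM, and Ltb4r1, a leukotriene B4 receptor gene, from 26.0 ± 1.603 to 19.6 ± 0.553 RPKM. Ccr6, the receptor for CCL20 carried by Th17 cells, rose from 23.0 ± 0.890 to 33.3 ± 1.31 RPKM, and Il22, which acts on epithelia, from 7.68 ± 0.249 to 10.5 ± 0.668 RPKM. Il22 passed in 9 of 18 alternatives (adjusted p from 0.0152 to 0.271) and did not pass with voom (0.0599). Adjusted over the list alone, 10 members were lower and 3 higher. The camera test placed the list lower than other genes (median log2 difference -0.20, adjusted p = 6.03e-05). The list had adjusted p = 0.208 with an estimated correlation.

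The signature cytokine gene Il17a measured 198 ± 22.3 RPKM in vehicle and 124 ± 17.8 RPKM in pemafibrate (n = 3 each), a log2 difference of -0.68 ± 0.11 that did not pass over all genes (limma adjusted p = 0.0717), although the groups did not overlap. Il17f, the most abundant Th17 cytokine transcript here, measured 1621 ± 83.8 against 1286 ± 130 RPKM (log2 difference -0.34 ± 0.08, limma adjusted p = 0.181). Rora, which encodes a nuclear receptor that promotes the Th17 programme, had a log2 difference of -0.21 ± 0.08 (limma adjusted p = 0.476). Ahr, a receptor for environmental ligands, measured 18.3 and 13.5 RPKM, with a limma adjusted p of 0.0721. With voom on the recovered reads Il17a passed (adjusted p = 0.00186), as did Il17f (0.0148), while across 18 alternatives the adjusted p ran from 0.00186 to 0.230 for Il17a and from 0.0148 to 0.642 for Il17f. In the authors' deposited table the adjusted p was 4.68e-12 for Il17a and 1.18e-06 for Il17f.

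**Figure D2:**
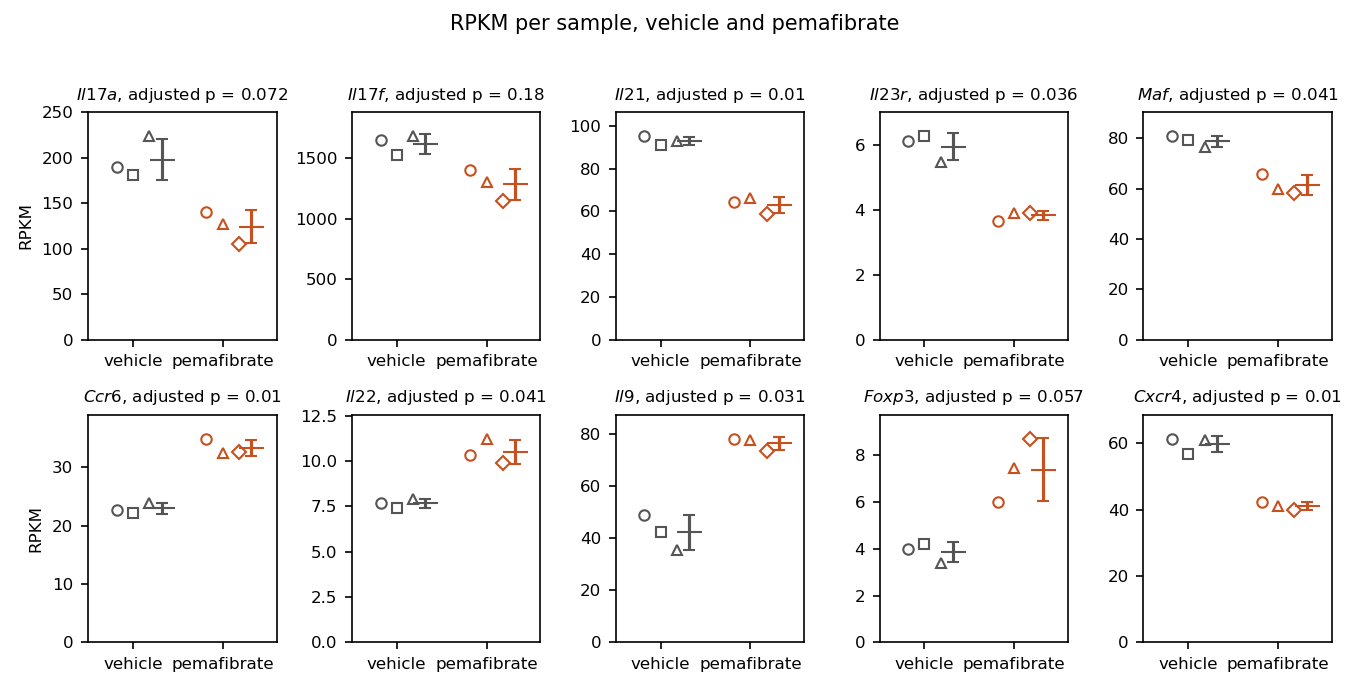
RPKM of 10 genes in each vehicle and pemafibrate sample (open symbols, with shape following the number in the title: circle 3, square 4, triangle 7, diamond 8), with the group mean ± SD (n = 3) beside them and the limma adjusted p above each panel. In every panel the 3 pemafibrate samples lie wholly above or below the 3 vehicle samples, but the adjusted p of Il17a, Il17f and Foxp3 is above 0.05.

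Genes tied to the less inflammatory Th17 state were lower as a group, but not apart from other lists. Maf and Ahr are also in the Th17 core list, and Il10 is also in the Treg and Th2 lists. These are the 3 members that voom called lower. In the non-pathogenic Th17 list Maf fell and Il9 rose, and the remaining tested members of 8 did not pass over all genes by limma, while voom called 4, 1 higher and 3 lower. Il10, an immunosuppressive cytokine gene, measured 40.7 ± 3.05 RPKM in vehicle and 27.5 ± 4.66 RPKM in pemafibrate (log2 difference -0.57 ± 0.11, limma adjusted p = 0.105). Adjusted over the list alone, 3 members were lower and 1 higher. By camera the list was lower (median -0.21, adjusted p = 0.0123), with adjusted p = 0.426 with an estimated correlation. Without vehicle 3 its adjusted p was 0.0530. In the pathogenic Th17 list limma called Il22 alone, as higher, among 15 tested, and voom called 1 other gene, Icos, as higher, with 4 higher and 3 lower adjusted over the list alone, and the list did not pass camera (adjusted p = 0.439). Csf2, the gene for the inflammatory cytokine GM-CSF, measured 4.35 and 4.44 RPKM (limma adjusted p = 0.954).

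Regulatory T cell genes were higher as a group. Izumo1r, which encodes folate receptor 4, rose from 19.0 ± 0.394 to 23.7 ± 0.694 RPKM (log2 difference 0.31 ± 0.04, limma adjusted p = 0.0362) and was the only one of 19 tested members of the Treg list to pass over all genes by limma, while voom called 6, 5 higher and 1 lower. Foxp3, the lineage-defining transcription factor gene (chromosome X, 7579676 to 7595243), measured 3.86 ± 0.424 RPKM in vehicle and 7.39 ± 1.34 RPKM in pemafibrate, a log2 difference of 0.85 ± 0.13 (limma adjusted p = 0.0573). Nrp1 measured 1.97 and 3.21 RPKM (limma adjusted p = 0.0603). Adjusted over the list alone, 7 members were higher and 2 lower, the latter pair being Il10 and Ctla4. Camera gave an adjusted p of 0.0249 (median 0.12), with adjusted p = 0.426 with an estimated correlation, 0.105 without vehicle 3 and 0.0647 without pemafibrate 3. Foxp3 passed with voom on the recovered reads (adjusted p = 0.00239) and ranged from 0.00239 to 0.261 over 18 alternatives.

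The TGF-beta target list was lower as a group by camera, while the one member called by limma, Ccr8, was higher. Voom called 2 of 12 tested members, Ccr8 as higher and Ski as lower (adjusted p = 0.0435). Ccr8, a receptor known from Th2 and regulatory T cells, rose from 59.6 ± 4.24 to 87.1 ± 3.19 RPKM (limma adjusted p = 0.0147). Ski and Tgif1, repressors of TGF-beta signalling, had log2 differences of -0.18 ± 0.04 and -0.17 ± 0.04, neither past the limma test over all genes. Adjusted over the list alone, 5 members were lower and 1 higher. The list's median was -0.10 (camera adjusted p = 0.0123), with adjusted p = 0.495 with an estimated correlation. Fry did not call it (adjusted p = 0.268), and camera lost the call without vehicle 7 (0.200), without pemafibrate 8 (0.175) and with array weights (0.0516).

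Among genes of other helper T cell types and of T cell activation, limma called 2 of 15 tested members of the Th1 list, 2 of 9 of the Th2 list, 2 of 10 of the Tfh list and 1 of 19 of the T cell activation list. Voom called 2, 3, 5 and 4, of which 0, 2, 3 and 3 were higher. Both called genes of the Th1 list fell, among them Il12rb2, a chain of the interleukin 12 receptor, from 39.3 ± 2.84 to 29.7 ± 1.22 RPKM (log2 difference -0.40 ± 0.06, limma adjusted p = 0.0492). Ifng and Tbx21, the Th1 cytokine and its master regulator, had limma adjusted p of 0.922 and 0.575. In the Th2 list Ccr4 and Ccr8 rose, Ccr4 from 112 ± 2.81 to 143 ± 2.93 RPKM (log2 difference 0.35 ± 0.04). Gata3 measured 2.01 and 2.73 RPKM (limma adjusted p = 0.309). In the Tfh list Sh2d1a rose and Il21 fell. Nr4a3, an orphan nuclear receptor induced by antigen receptor signals, rose in the T cell activation list from 9.20 ± 0.163 to 12.5 ± 0.504 RPKM (limma adjusted p = 0.0314). Adjusted over the list alone, 3 higher and 4 lower genes were found for Th1, 3 and 1 for Th2, 4 and 2 for Tfh, 3 and 1 for T cell activation, and 3 and 2 for naive and memory T cell genes, of which none passed over all genes by limma (7 at unadjusted p under 0.05, 1 by voom). None of these lists passed camera, with adjusted p of 0.782, 0.472, 0.526, 0.782 and 0.389 in that order, but the Th2 list passed fry (adjusted p = 0.0345). The T cell activation list had a median of -0.06 and a mean of 0.0056, and camera placed it lower.

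The drug's receptor was hardly detected, and limma called none of its known target genes over all genes. Per the labels treatment ran until day 2 and culture for 2 days more, so an earlier response of these genes was not measured. Ppara had 0, 1 and 1 reads in vehicle 3, 4 and 7 and 2, 1 and 0 in pemafibrate 3, 7 and 8, and Pparg had 2, 1 and 1 against 2, 5 and 1, so a difference in either was not detectable at this depth. Ppard, the gene of the third family member, measured 14.98 ± 0.684 and 15.1 ± 0.618 RPKM (limma adjusted p = 0.984). Pdk4 had 0 reads in all libraries. Among 33 tested PPARalpha target genes limma called 0, with 4 at an unadjusted p under 0.05 (3 higher and 1 lower), 1 by voom, and 1 higher adjusted over the list alone. That gene, Abcd3, a peroxisomal fatty acid transporter, measured 14.8 and 18.3 RPKM (log2 difference 0.30 ± 0.05, limma adjusted p = 0.0860). Cd36, a fatty acid uptake receptor, measured 0.731 ± 0.124 and 1.32 ± 0.230 RPKM without overlap of the groups (log2 difference 0.56 ± 0.15, limma adjusted p = 0.223). Pex11a, the lower one of the 4, measured 2.42 and 1.66 RPKM (log2 difference -0.45, limma adjusted p = 0.324). In the authors' deposited table the adjusted p was 0.000674 for Abcd3, 0.00281 for Cd36 and 0.657 for Pex11a. The mitochondrial carnitine palmitoyltransferase gene Cpt1a had a log2 difference of 0.07 ± 0.05, Acaa2 of 0.19 ± 0.07, Angptl4 of 0.06 ± 0.08, Plin2 of -0.03 ± 0.08 and Slc25a20 of -0.0018 ± 0.045. Rxra, a partner of PPAR receptors, measured 10.1 and 12.5 RPKM (log2 difference 0.29 ± 0.05, limma adjusted p = 0.0721). Rxrb, another partner, measured 31.2 and 30.1 RPKM (log2 difference -0.05, limma adjusted p = 0.757). Of 9 tested receptors and partners limma called 0 over all genes (2 at unadjusted p under 0.05, 1 by voom). Adjusted over the list alone, Rxra was the 1 higher gene. Of the 33 tested target genes, 23 had a log2 difference above 0 and 10 below, with a median of 0.02. The target list did not pass camera (adjusted p = 0.319) and passed fry (adjusted p = 0.0345), which asks whether its genes move one way on balance. The receptor list did not pass camera (adjusted p = 0.782).

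Genes of cholesterol synthesis, the respiratory chain and the ribosome were higher as groups by very small amounts. Of 24 tested cholesterol synthesis genes 23 had a log2 difference above 0, with a median of 0.09. Stard4, a sterol carrier, measured 41.4 and 45.9 RPKM. Of 41 oxidative phosphorylation genes 36 were above 0, with a median of 0.05, and Ndufa4 measured 284 and 319 RPKM. Of 38 ribosomal protein genes 32 were above 0, with a median of 0.06. In these 3 lists limma called 0 genes over all genes and 0 adjusted over the list alone, with 1, 5 and 0 at an unadjusted p under 0.05 and 0 by voom. Camera called the lists with adjusted p of 0.00149, 0.000935 and 0.0123 at the preset correlation of 0.01. The estimated correlations between their genes were far higher, at 0.41, 0.39 and 0.53, and with them each list had adjusted p = 0.790. The 3 lists had no call by fry (0.522, 0.522 and 0.646). Cholesterol synthesis lost its call without vehicle 7 (0.267) and without pemafibrate 8 (0.0616), and the other lists lost theirs without vehicle 4 (0.170 and 0.452), without pemafibrate 3 (0.123 and 0.499) and after removal of a gene length trend (0.112 and 0.173).

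**Figure D3:**
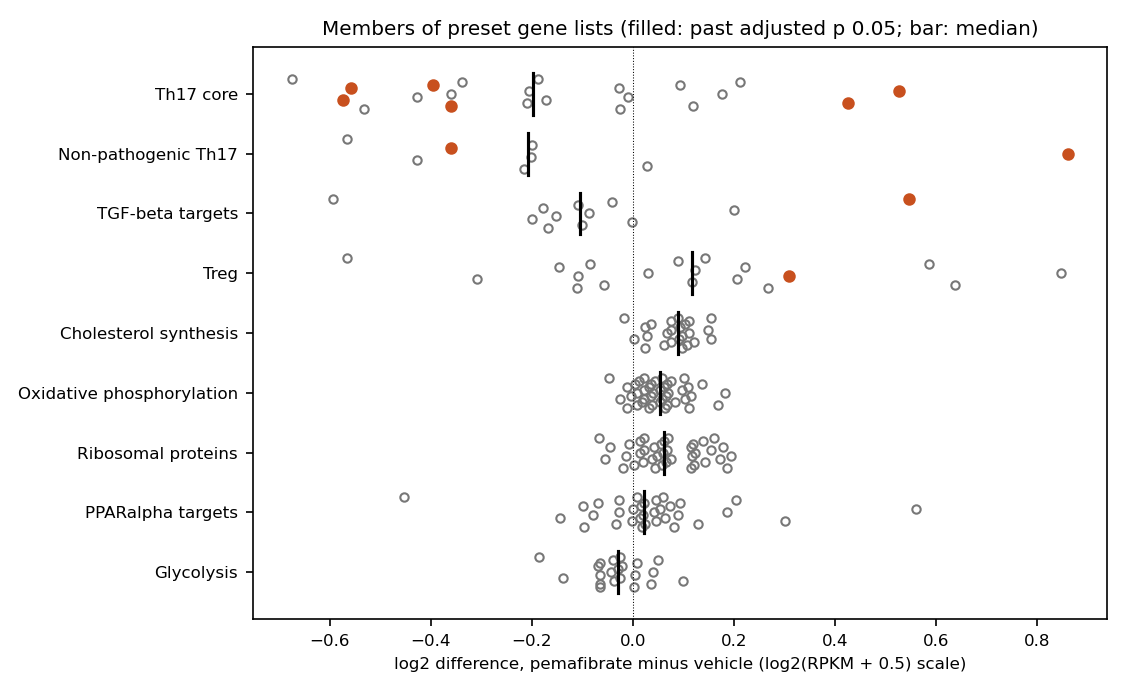
Log2 difference between pemafibrate and vehicle (horizontal axis, on the log2(RPKM + 0.5) scale) of each tested member of 9 preset gene lists, with filled points for genes past an adjusted p of 0.05 and a bar at the list median. Th17 core members spread from Il17a at -0.68 to Ccr6 at 0.53, while the medians of the cholesterol synthesis, oxidative phosphorylation and ribosomal protein lists lie at 0.09, 0.05 and 0.06.

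In the lists of glucose, growth and stress genes limma called 1 gene, Nupr1. Hk2 and Ldha of glycolysis had log2 differences of 0.04 ± 0.05 and 0.0075 ± 0.083, the glucose transporter gene Slc2a1 of -0.07 ± 0.09, the fatty acid synthase gene Fasn of 0.05 ± 0.07 and the proliferation marker gene Mki67 of -0.00025 ± 0.049. In the ATF4 stress response list Nupr1 rose among 17 tested members, with 3 at an unadjusted p under 0.05, 2 by voom (Nupr1 and Phgdh, both higher), and 2 higher and 1 lower adjusted over the list alone, and the list did not pass camera (adjusted p = 0.782), its median (-0.0084) and mean (0.05) differing in sign. Among hypoxia genes limma called 0 of 17, with 1 at an unadjusted p under 0.05, 1 by voom and 1 lower adjusted over the list alone (camera adjusted p = 0.184). The interferon response list had 0 of 12 called, 2 at an unadjusted p under 0.05, 0 by voom and 1 higher adjusted over the list alone (camera adjusted p = 0.526). The JAK-STAT feedback list had 0 of 12 called, 1 at an unadjusted p under 0.05, 0 by voom and 1 lower adjusted over the list alone (camera adjusted p = 0.991). In 16 further lists limma called 0 of 182 members, with 10 at an unadjusted p under 0.05, 0 by voom and 0 adjusted over the list alone. These were glycolysis, fatty acid synthesis, glutamine and amino acid uptake, the unfolded protein response, heat shock, the G2/M and S phases of the cell cycle, p53 targets, NF-kB inflammation, and the markers of B cells, neutrophils, dendritic cells, CD8 T cells, erythroid cells, platelets and T cells in general. None with a camera test passed it, and NF-kB inflammation genes had a median of 0.0033 and a mean of -0.0018, which differ in sign.

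Of 32 tested markers of other spleen cells limma called 0, with 7 at an unadjusted p under 0.05 and 2 by voom, 1 higher and 1 lower. The pan T cell marker Cd2 measured 587 and 583 RPKM in vehicle and pemafibrate, against 1.93 and 2.01 RPKM for the B cell gene Cd79a, 6.20 and 6.25 RPKM for the macrophage gene Lyz2, 12.5 and 13.9 RPKM for Cd74 of antigen-presenting cells, and 1.497 and 1.17 RPKM for the neutrophil gene S100a8. Bst2, listed for dendritic cells but also present in other cells, measured 80.0 and 78.2 RPKM. Klrc1, a natural killer cell receptor gene, measured 12.2 and 16.6 RPKM (log2 difference 0.42 ± 0.09, limma adjusted p = 0.131), with a voom adjusted p of 0.0268. The natural killer cell list had 0 of 7 called by limma, 4 at an unadjusted p under 0.05, 1 by voom, and 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.526). The macrophage list had 0 of 4 called, 1 at an unadjusted p under 0.05, 1 by voom and 1 lower adjusted over the list alone. Gamma-delta T cell markers had 0 tested members, and transcripts of the mitochondrial genome were not analysed here.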

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

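The tests on voom, the filter at 10 recovered reads and the gene length trend were chosen after the data were seen. The count of 40 genes moved to 7 with no filter, where 16822 genes were tested, to 140 with array weights, to 148 with voom on recovered reads, to 100 at an adjusted p under 0.1, to 11 with a 1.5-fold minimum, and to between 0 and 25 without one library. Voom shared 37 of its genes with the 40, array weights 40. Apart from the title number as a block, the other settings gave 38 to 57 genes. The planned edgeR and DESeq2 alternatives were not run on reads rebuilt from RPKM; voom took their place. Titles share only the numbers 3 and 7, with correlations of the deviations from the group mean of 0.030 and -0.0083. Other pairs between the groups ran from -0.22 to 0.20, so these values show no pairing but cannot exclude a shared animal or culture. The title number as replicate block compares the groups through the numbers 3 and 7 only. With it limma called 0 genes (653 at unadjusted p under 0.05) and 6 lists, without TGF-beta targets (0.235). Leaving out a library leaves fewer samples; the cause of the other shifts was not tested. Camera called 7 lists, 0 with an estimated correlation (3 at unadjusted p under 0.05, lowest adjusted p 0.208), and 5 or 6 with array weights or the length trend removed, and 5 to 7 without one library. The estimates were 0.41, 0.39 and 0.53 for cholesterol synthesis, oxidative phosphorylation and ribosomal proteins, against the preset 0.01. For Th17 core, non-pathogenic Th17, Treg and TGF-beta targets they were -0.016, -0.080, -0.038 and 0.049. For Th17 core, non-pathogenic Th17 and Treg the estimate lay below the preset 0.01. Their larger p with an estimated correlation therefore does not come from more correlated genes. Fry called 5, of which 3 (Th17 core, non-pathogenic Th17, Treg) were among the 7, besides PPARalpha targets and Th2. The Th17 core list passed in 18 of 19 alternatives. Glycolysis genes passed lower without vehicle 3 (0.0388) and without pemafibrate 3 (0.0286), and hypoxia genes without vehicle 3 (0.0118), vehicle 4 (0.0307) and pemafibrate 3 (0.0149). Depth limits genes such as Ppara, with at most 2 reads per library.

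Signs turned only for lists and genes that had not passed in the main fit, and the cause was not tested. Glycolysis and hypoxia, which passed lower without some libraries, turned to 0.049 and 0.060 without vehicle 7. Such values are about as large as the medians of the called oxidative phosphorylation (0.05) and ribosomal protein (0.06) lists. List medians turned to -0.033 (Tfh) and 0.013 (ATF4) with no filter, -0.022 (interferon) and -0.0022 (NF-kB) at 2 RPKM, -0.00074 (NF-kB) with median ratio scaling, -0.0080 (NF-kB) and -0.0067 (JAK-STAT) with quantile normalization, and -0.0047 (NF-kB) without the length trend. With array weights they turned to 0.013 (glycolysis), 0.0048 (hypoxia), -0.012 (NF-kB) and 0.00016 (pan T), and Slc2a1 to 0.0037. With the block they turned to 0.013 (ATF4) and -0.0022 (NF-kB), Plin2 to 0.0095 and Mki67 to 0.012, the last also to 0.0032 without the length trend. Without one library, list medians ranged from -0.036 to 0.043 (PPAR receptors and partners), -0.043 to 0.028 (ATF4 stress response), -0.078 to 0.049 (Glycolysis), -0.098 to 0.060 (Hypoxia), -0.0063 to 0.037 (Glutamine and amino acid uptake), -0.0088 to 0.030 (Cell cycle G2/M), -0.045 to 0.079 (p53 targets), -0.063 to 0.053 (NF-kB inflammation), -0.033 to 0.045 (JAK-STAT feedback) and -0.0023 to 0.022 (Fatty acid synthesis). Gene log2 differences ranged from -0.018 to 0.043 (Ppard), -0.021 to 0.028 (Slc25a20), -0.00099 to 0.091 (Hk2), -0.044 to 0.090 (Ldha), -0.043 to 0.033 (Mki67), -0.12 to 0.031 (Plin2), -0.045 to 0.067 (Csf2), -0.13 to 0.031 (Slc2a1), -0.077 to 0.23 (Ifng) and -0.011 to 0.12 (Fasn).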

Other observations

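Chemokine receptor genes were looked at as a family after several were seen among the called genes, so their number is a description and not a test; the tests of Th17 cell share, other cell types and gene length for the lists below were also chosen after the result was seen. Of 13 tested chemokine receptor genes limma called 5, 3 higher and 2 lower, with Ccr4, Ccr6 and Ccr8 among the former and Cxcr4 among the latter, while voom called 8, 3 higher and 5 lower. Ccr2, the receptor for CCL2, measured 3.16 and 2.099 RPKM in vehicle and pemafibrate (log2 difference -0.49 ± 0.11, limma adjusted p = 0.153, voom 0.0321). Ccr1 measured 0.922 and 0.404 RPKM (limma adjusted p = 0.171, voom 0.0343), and Cxcr5, the receptor that leads T cells to B cell follicles, 6.19 and 4.597 RPKM (limma adjusted p = 0.0706, voom 0.0312).

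Further called genes outside the naming rule, chosen after their values were seen, were Timp1, an inhibitor of metalloproteinases, which fell from 349 to 246 RPKM, and Id2, an inhibitor of E proteins, which fell from 126 to 101 RPKM. Mgll, the monoacylglycerol lipase gene, fell from 6.28 to 4.33 RPKM, while Gpr55, a receptor for lysophospholipids, rose from 5.74 to 7.65 RPKM. Procr, the endothelial protein C receptor gene, fell from 71.1 to 55.7 RPKM, and Itga3, an integrin chain, from 39.4 to 30.8 RPKM. Each of these had non-overlapping groups and a limma adjusted p under 0.05.

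With 6 samples there are 10 splits, too few for a share under 0.05. The real split gave 40 genes and the highest other split 1, so 1 of the 10 gave as many. For lists the real split gave 7 and the highest other 10, and 3 of the 10 gave as many. The TGF-beta target list had a smaller camera p in the split of vehicle 3, pemafibrate 7 and pemafibrate 8 from the rest (0.00170) than in the real split (0.00223).

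By camera the Th17 core list was lower and the Treg list higher, with adjusted p = 0.208 and adjusted p = 0.426 with an estimated correlation. Those estimates, -0.016 and -0.038, lay below the preset 0.01, so more correlated genes are not what raised these p-values. A uniformly lower share of Th17 cells would lower every called member only if the cells in their place made less of each RNA, which was not measured. Limma called 2 members higher, Il22, which voom did not call (adjusted p = 0.0599), and Ccr6, which it did (0.000253). Ccr6 had an adjusted p from 0.000253 to 0.156 over 18 alternatives, with 0.0748 without vehicle 3 and 0.0641 without pemafibrate 7. The 2 genes go against a lower share as the whole cause only under that condition, so a lower share stays open. Removal of the gene length trend left the Th17 list at an adjusted p of 5.62e-05, so that trend as the whole cause is argued against. Cells of other spleen types cannot be told apart from a change within T cells for the Treg list, since 20 markers of B cells, macrophages, neutrophils, dendritic and erythroid cells had a median log2 difference of 0.042 (0 called by limma, 2 at an unadjusted p under 0.05, 1 by voom) against 0.12 for the Treg list, the 95% bootstrap interval of the difference, over list members, ran from -0.14 to 0.21, and the natural killer and CD8 T cell marker lists, outside that test, had medians of 0.14 and 0.14. A change in T cell state after pemafibrate stays open as a hypothesis and was not tested separately.

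The cholesterol synthesis, oxidative phosphorylation and ribosomal protein lists were higher by camera, each with adjusted p = 0.790 with an estimated correlation and with no call by fry (0.522, 0.522 and 0.646). After removal of the length trend the oxidative phosphorylation median went from 0.05 (quartiles 0.02 and 0.07) to 0.02 (-0.02 and 0.06) and the ribosomal median from 0.06 (0.02 and 0.12) to 0.03 (-0.0076 and 0.08), and the call ended as the shift shrank, with a lowest adjusted p of 0.112, so a length trend between libraries may account for them. Cholesterol synthesis kept its median of 0.09 and, at the preset correlation, an adjusted p of 0.000723, which argues against that trend as its whole cause. In 1 other split, of vehicle 3, vehicle 7 and pemafibrate 3 from the rest, all 3 lists had a camera p as small as in the real split, so variation between libraries that does not follow treatment may account for them, cholesterol synthesis included. An effect of pemafibrate on these genes stays open.

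The split of vehicle 3, vehicle 4 and pemafibrate 8 from the other libraries gave 1368 genes at an unadjusted p under 0.05, above the 1098 of the real split. It was singled out as the highest of the 10 splits, and 1 gene passed an adjusted p of 0.05 in it. The remaining splits gave 214 to 997 genes, so such counts vary widely between splits. A structure of the samples that the labels do not name may lie behind the 1368, but this count alone cannot show it. Removal of a gene length trend left 1265 and removal of a GC trend 1353, above the 568 expected by chance. The count changed little, so neither trend accounts for most of it. What, if anything, parts these libraries stays open, and no biological explanation was tested.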
